A study of Homo sapiens with 4 samples.

How the data were processed

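The series measured gene expression in FaDu, an established human cell line from a squamous cell carcinoma of the hypopharynx, with Affymetrix arrays. Per the labels, cells grew for 48 h with a matching volume of water, with chelidonine at 10 µM or with chelidonine at a dose named EC50. Chelidonine is an alkaloid of the greater celandine plant. The labels give no concentration for the EC50 dose and do not say which effect it refers to, so no order of the 2 doses was assumed. Of the 4 arrays, 2 were of untreated cells, 1 of the EC50 dose and 1 of 10 µM. Another arm that the labels' treatment protocol mentions was not analysed here. The labels do not say that the arrays came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

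The deposited values are log2 expression values per probe set, 1 column per array, for 49395 probe sets. Per the labels' protocols, total RNA was amplified and labelled with biotin, and per the submitters' processing notes the arrays were processed with Affymetrix Expression Console. The version, the background correction, the summarization and the normalization are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.92 to 15.0. The sorted values of each array deviated from their mean over the 4 arrays by at most 0.08 (log2), so the arrays had been brought to nearly equal distributions before deposit. Such scaling can hide a change shared by most genes, and every difference below is relative to the array as a whole. No depth exists for such values, and the number of arrays limits the precision.

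Control probe sets, 102 in number, were left out of the tests. Of the other 49293, 44988 carried 1 gene symbol in the platform's annotation, 1832 carried several and 2473 had none. The gene identifiers of 44961 of the 44988 matched a RefSeq gene, and 0 symbols needed updating. Probe sets with several symbols or none were not used for genes. Each of 18132 genes was represented by its probe set with the highest mean over the 4 arrays. A gene was tested when that mean was above 6.61 (log2), the median of the means of all non-control probe sets, which left 10126 genes. Of 5982 genes with 2 or more probe sets above this level, 7 had probe sets whose 10 µM differences reached 2-fold one way and 1.41-fold the other way.

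Each dose was compared with untreated cells, and the doses with each other, by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) on a fit of 3 group means to all 4 arrays. Its 1 residual degree of freedom came from the untreated pair, and the prior added 6.99 degrees of freedom, so each lone dose array is assumed to vary like the untreated arrays. Both chelidonine arrays together were compared with the untreated pair in a fit of 2 group means, with 2 residual and 4.86 prior degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and are two-sided. A rule of size without a test counted genes at least 2-fold from each untreated array in the same direction. Between doses it counted genes at least 2-fold apart and further apart than the untreated pair.

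Gene lists, 55 in number, were written from textbook knowledge, 7 of them markers of cells that a FaDu culture should not hold. The 49 lists with 5 or more measured members were described by the median of their log2 differences. Each median was placed among 10000 random lists of the same size drawn from the same of 20 bins of mean expression. Lists were also tested for both chelidonine arrays against the untreated pair with limma's camera, with a preset correlation of 0.01 and with an estimated one. The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, per dose and direction, the 10 genes with the largest difference from the nearer untreated array, and up to 4 members of each list with the largest mean absolute difference over both doses. The genes past the threshold at 10 µM that the size ranking left out were added after their values were seen.

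Unchanged arrays sharing the untreated pair were simulated 100 times to give values without an effect. The tests were also tested on simulated data, 20 data sets of 10126 genes with 200 changed genes each. The 10 µM test found 42.5% of genes changed by 1 (log2), 98.8% of those changed by 2 and 99.9% of those changed by 3. Of its calls, on average 183 per data set, 22.3 or 12.2% were false, above the nominal level. This share depends on the 200 changed genes put in, so it does not carry over to the genes called here. The prior estimated in these simulations ranged from 6.06 to 71.5 degrees of freedom. The EC50 test found 42.5%, 99.4% and 100%, with 11.7% false calls, and the test of both arrays 64.2%, 99.4% and 100%, with 4.90% false calls. Random lists of 20 genes shifted by 0.3 (log2) lay above the 97.5th percentile in 99.5% of 200 draws, and unshifted ones lay outside the central 95% in 4% of draws. The share for unshifted lists follows from drawing their members at random. It does not show how lists of genes that vary together behave.

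Alternatives were quantile and cyclic loess normalization, no filter, a filter at 5.93 (log2), the 95th percentile of 368 olfactory receptor probe sets, the mean of a gene's probe sets, probe sets marked as shared between transcripts left out, other variance priors, other fold thresholds and each array left out. No genome position is given, because the files name no genome build.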

Results

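Expression was measured on 4 arrays of FaDu cells, a squamous carcinoma line of the hypopharynx, after 48 h. The groups were untreated cells (2 arrays), cells given chelidonine at its EC50 dose (1 array) and cells given 10 µM chelidonine (1 array). The study asked how this plant alkaloid affects gene expression in the line. On each array 11493 to 11752 genes lay above the level of olfactory receptor probe sets, taken as not expressed. The EC50 array stood apart in its control probe sets. Its beta-actin signal at the 3′ end exceeded that at the 5′ end by 0.98 (log2), against 0.58 to 0.68 on the other 3 arrays. The GAPDH difference was 0.18 there, against 0.06 to 0.10 elsewhere. Its poly-A spikes, added before amplification, averaged 6.90 (log2), against 7.54 to 7.82 elsewhere. The untreated arrays differed from each other by a standard deviation of 0.33 (log2) over 10126 genes, and 132 genes differed at least 2-fold between them.

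At 10 µM chelidonine, the secreted protease genes MMP3 and MMP1 and the cytokine gene IL11 rose, and the squamous epithelial genes SERPINB13, KLK10 and KRT5 fell. MMP3, a matrix-degrading protease, rose 15.2-fold, from a mean of 6.95 ± 0.04 (log2, SD, n = 2) to 10.88. STC1, a secreted glycoprotein hormone, rose 10.8-fold, and the interstitial collagenase gene MMP1 rose 3.30-fold. SERPINB13, a protease inhibitor of squamous epithelium, fell 9.82-fold, from 9.26 ± 0.46 to 5.96, although its 3 probe sets ranged from −3.30 to −1.52 (log2 difference). KRT5, the basal keratin of stratified epithelia, fell 2.61-fold from 13.30 ± 0.12 on the log2 scale.

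In all, 15 genes rose and 4 fell past an adjusted p of 0.05 by limma, of 10126 tested. After quantile normalization only 2 rose and 0 fell past it. The smallest change among the 19 genes called was 2.54-fold. At an unadjusted p under 0.05 there were 894 genes, 512 higher and 382 lower, where chance alone gives 506 in total. Besides MMP3 (log2 difference 3.93 ± 0.23, standard error, adjusted p = 0.00159), STC1 (3.43 ± 0.34, adjusted p = 0.0173) and MMP1 (1.72 ± 0.20, adjusted p = 0.0222), the higher genes included DHRS2, a short-chain dehydrogenase (3.05 ± 0.24, adjusted p = 0.00694). The cytokine gene IL11 rose by 2.06 (adjusted p = 0.0373), the Ras-induced membrane protein gene TMEM158 by 2.77 and the exonuclease gene ISG20 by 2.06. AADAC, an esterase, rose by 1.92, the potassium channel gene KCNMA1 by 1.85, the histone gene H2BC12 by 1.77, the collagen VI gene COL6A1 by 1.76 and the cytidine deaminase gene APOBEC3B by 1.35. The hair keratin-associated gene KRTAP2-3 rose by 2.33, FAM25A by 2.23 and KHDC1L by 1.94. Of the lower genes, ALDH3A1, an aldehyde dehydrogenase of epithelia, fell by 2.06 and KLK10, a kallikrein of keratinocytes, fell by 2.03, both at adjusted p = 0.0201. SERPINB13 fell by 3.30 (adjusted p = 0.0169) and KRT5 fell by 1.38 (adjusted p = 0.0201). COL6A1 rests on 1 of 2 probe sets above the filter, since these differed by 1.76 and 0.17 (log2). FAM25A, KRTAP2-3, APOBEC3B and H2BC12 have near-identical family members, whose signal the probe sets may share. MMP3 and TMEM158 each have only 1 probe set, marked as shared between transcripts. FAM25A, IL11, IL1RL1, AKR1B10 and IFI44L lay under the olfactory receptor level on at least 1 array, so their exact differences rest partly on background signal.

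**Figure D1:**
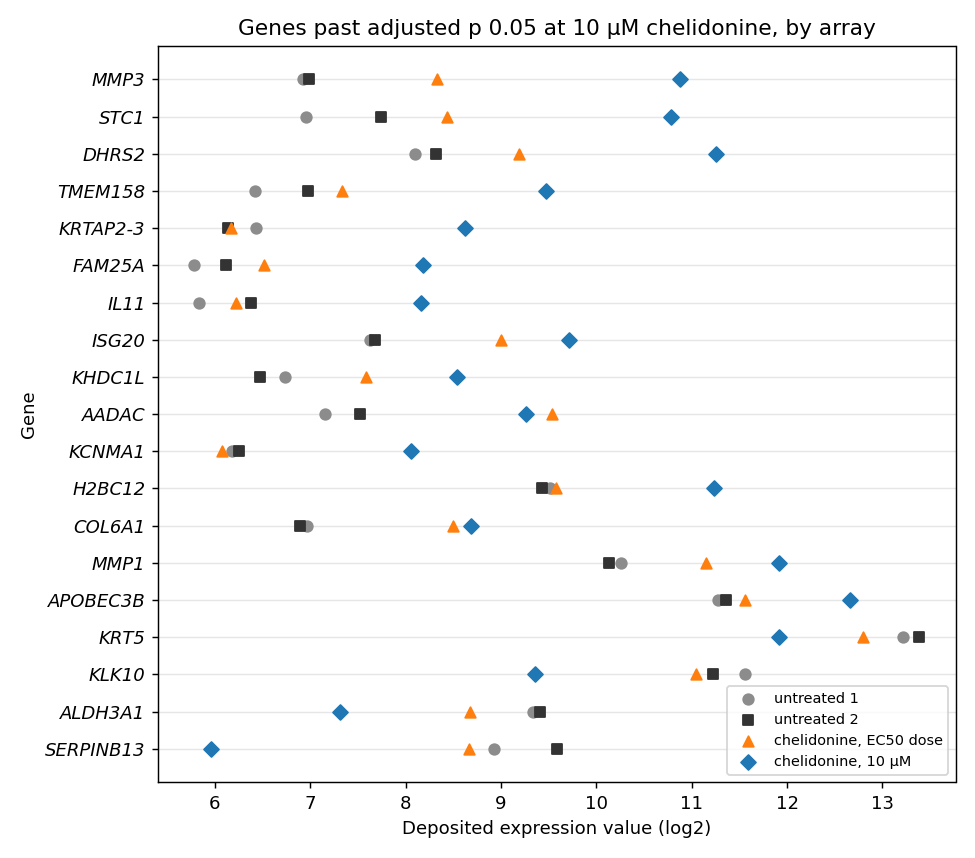
Deposited log2 expression value (horizontal axis) of the 19 genes past adjusted p 0.05 at 10 µM (vertical axis), with 1 point per array for untreated 1, untreated 2, the EC50 dose and 10 µM. The 10 µM point lies at least 2-fold from both untreated points for 19 of 19 genes, and the EC50 point lies between the untreated points and the 10 µM point for 15 of 19. For 1 array against 2, chance puts 33.3% of genes beyond both on a given side. These genes were chosen by their distance from the same untreated arrays, so the count of 15 is no test of a graded response.

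By the rule of size, 79 genes were at least 2-fold higher and 34 at least 2-fold lower at 10 µM than on each untreated array, where simulated unchanged arrays gave 9.02 and 8.46. Against untreated 1 alone the counts at 10 µM were 244 and 113, and against untreated 2 alone 116 and 54. The simulated counts may be low, since 81.6 genes differed at least 2-fold within simulated pairs and 132 within the real untreated pair. Among those ranked highest without passing the test were the interleukin 33 receptor gene IL1RL1 (3.33 higher, adjusted p = 0.0856, probe sets from 1.40 to 3.33), the ectonucleotidase gene NT5E (2.70 higher, adjusted p = 0.0927) and the fibronectin gene FN1 (2.44 higher, adjusted p = 0.106). The untreated arrays differed for these 3 genes, with SDs of 1.15, 0.92 and 0.85 (log2). Among the lowest without passing were complement factor B, CFB (−1.54, adjusted p = 0.0695), the interferon-induced TRIM22 (−1.65, adjusted p = 0.0927), the immediate early gene EGR1 (−1.67, adjusted p = 0.0786) and the basal keratin KRT15 (−1.41, adjusted p = 0.0879). IGFL1 was at −1.75 (adjusted p = 0.126) and SERPINA3, an acute-phase protease inhibitor, at −1.49 (adjusted p = 0.114).

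Matrix proteases and their inhibitors lay highest of the lists at 10 µM, with a median log2 difference of 0.69 over 21 genes (percentile 100 among matched random lists). It was 0.92 against untreated 1 and 0.43 against untreated 2, and the list was 0.17 higher within the untreated pair (percentile 99.1). Of these, 2 rose past the test over all genes, and 9 were higher and 1 lower when adjusted over the list alone. The stromelysin MMP10 was 1.43 higher and the aggrecanase ADAMTS1 1.55 higher, neither past the test. Hypoxia response genes had a median of 0.27 over 20 genes (percentile 100). Of these, 15 were higher than on both untreated arrays, 0 passed over all genes and 7 were higher when adjusted over the list alone. For 1 array against 2, chance puts 33.3% of genes above both. NDRG1, a hypoxia-induced gene, was 1.05 higher and ANGPTL4, a lipase inhibitor, 1.03 higher. Genes of G2/M and mitosis had a median of 0.27 over 43 genes (percentile 100), with 35 of them above both untreated arrays and 0 past the test. TOP2A, which untangles DNA for mitosis, was 0.48 higher (probe sets from 0.05 to 0.48) and the kinetochore gene NUF2 0.88 higher. At the EC50 dose these genes were also higher, by 0.66 and 0.39. The list's median there was −0.16, with 24 members below and 12 above both untreated arrays. Autophagy genes had a median of 0.22 (percentile 99.3), led by MAP1LC3B, the autophagosome protein LC3B, at 0.82 higher.

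Targets of the oxidative stress factor NRF2 lay lowest, with a median of −0.46 over 25 genes (percentile 0). Of these, 20 were lower than on both untreated arrays, 0 passed over all genes, and 11 were lower and 2 higher when adjusted over the list alone. PIR was at −1.33 and the aldo-keto reductase AKR1B10 at −1.47, while HMOX1, which breaks down heme, was 1.93 higher (adjusted p = 0.126). Cholesterol biosynthesis genes had a median of −0.27 over 18 genes (percentile 0.01), 14 of them lower than on both untreated arrays and 0 past either adjustment. The sterol enzymes DHCR7 and MVD were at −0.34 and −0.29. Fatty acid synthesis and lipid storage genes had a median of −0.25 over 17 genes (percentile 0.03), or −0.15 and −0.18 against untreated 1 and 2. In that list the desaturase SCD was at −0.95, while PLIN2, which coats lipid droplets, was 1.15 higher. Basal squamous genes had a median of −0.16 over 13 genes (percentile 1.79), or −0.26 against either untreated array, with KRT5 past the test. Epithelial junction genes had a median of −0.12 over 26 genes (percentile 0.57), with CLDN1, a tight junction protein, at −1.08. DNA repair genes had a median of −0.15 over 25 genes (percentile 0.17).

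Several lists at 10 µM depended on the untreated array they were set against. Targets of TGF-beta had a median of 0.90 above untreated 1 and 0.11 above untreated 2. Keratinocyte differentiation genes lay at −0.69 and 0.07, interferon-stimulated genes at −0.26 and 0.20, NF-kB and inflammatory cytokine genes at 0.41 and −0.12, and genes of the ATF4 stress response at 0.34 and −0.34. Secreted factors of senescence, among them MMP3, STC1, MMP1 and IL6, lay at 1.05 and 0.33. Of the 16 such genes measured, 3 rose past the test over all genes and 7 were higher when adjusted over the list alone. Targets of p53 lay 0.35 above untreated 1 and 0.06 above untreated 2, with CDKN1A, a cell cycle inhibitor, 0.93 higher. Replication-dependent histone genes, by contrast, lay 0.21 above untreated 1 and 0.34 above untreated 2, with a median of 0.34 (percentile 100) that became −0.31 without probe sets shared between transcripts. Pro-apoptotic genes (median 0.05, percentile 69.6), anti-apoptotic genes (0.11, percentile 84.7) and tubulin genes (0.07, percentile 80.1) lay inside the central 95%.

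In total 24 of 49 lists lay outside the central 95% at 10 µM, where chance gives 2.45, but 21 also did so for untreated 2 minus untreated 1. After quantile normalization limma called 2 higher and 0 lower genes, although the log2 differences of the 19 genes moved by at most 0.05. Without a filter it called 72 higher and 9 lower, and with the mean of each gene's probe sets 9 higher and 3 lower.

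**Figure D2:**
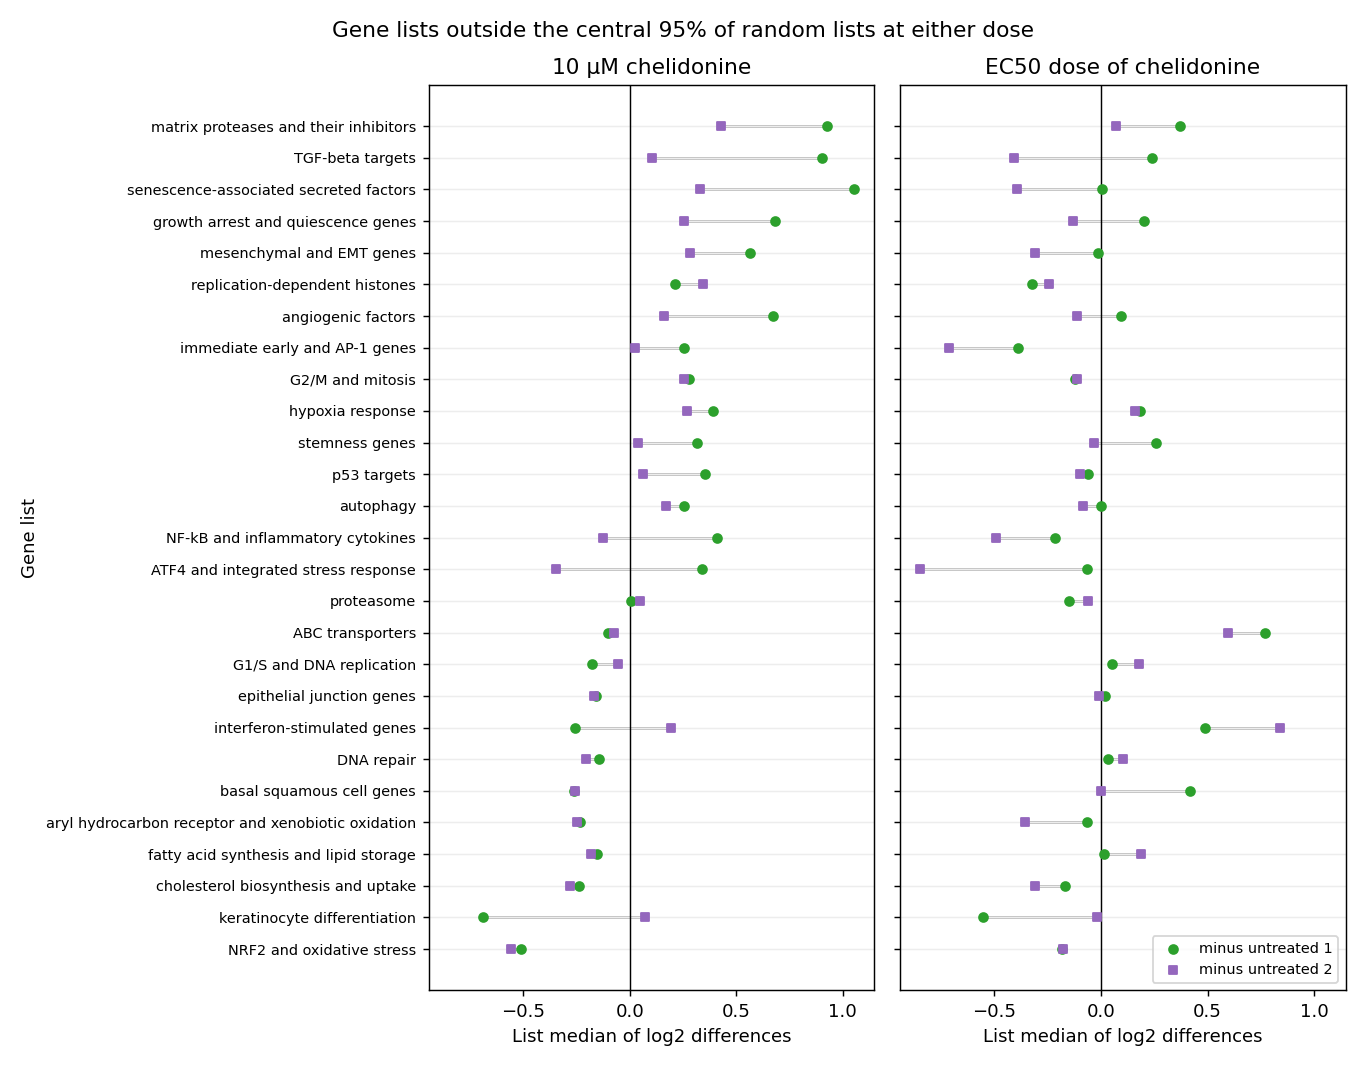
Medians of log2 differences (horizontal axis) of the 27 gene lists outside the central 95% of matched random lists at either dose (vertical axis), at 10 µM (left) and the EC50 dose (right), with circles for the difference from untreated 1, squares for that from untreated 2 and a line joining them. At 10 µM the median of NRF2 targets was −0.51 and −0.55, whereas that of interferon-stimulated genes was −0.26 and 0.20.

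On the EC50 array more genes were at least 2-fold higher than both untreated arrays than were lower, although none passed the test. CORO6, a coronin that binds actin, was 5.16-fold higher, at 9.92 against 7.55 ± 0.39 (log2, SD, n = 2). AADAC was 4.56-fold higher, and the golgin gene GOLGA8A, which has near-identical family members, 4.52-fold higher, with probe sets from 1.02 to 2.18 (log2). CCN2, a matricellular growth factor and YAP target, was 4.69-fold lower, at 7.69 against 9.92 ± 0.04. The immediate early genes FOS and EGR1 were 3.92-fold and 3.31-fold lower. These values stand beside the stronger 3′ signal and weaker poly-A spikes of this array, 0.98 and 6.90 (log2).

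At this dose limma called 0 genes past adjusted p 0.05, and the smallest adjusted p was 0.0605. At an unadjusted p under 0.05 there were 1261 genes, 1043 higher and 218 lower, where chance alone gives 506 in total. By the rule of size, 149 genes were at least 2-fold higher and 6 at least 2-fold lower than on each untreated array, where simulated unchanged arrays gave 9.02 and 8.46. Against untreated 1 alone these counts were 256 and 13, and against untreated 2 alone 333 and 78. Besides CORO6 (log2 difference 2.37 ± 0.29, standard error), GOLGA8A (2.18 ± 0.25) and AADAC (2.19 ± 0.26), the highest included the choline transporter-like gene SLC44A5 (1.90), the death receptor gene TNFRSF25 (1.78), the Fanconi anemia helicase gene FANCM (1.77) and RSRP1 (2.07). CAPRIN2 was 1.91, EPM2AIP1 1.78 and the helicase gene ZGRF1 1.68 higher. The 2 probe sets of TNFRSF25 differed, at 1.78 and 0.28. The lowest were CCN2 (−2.23 ± 0.23), FOS (−1.97 ± 0.35), EGR1 (−1.73 ± 0.27), the ATPase RUVBL1 (−1.30 ± 0.22), the glutathione-degrading CHAC1 (−1.71 ± 0.43) and the chemokine CCL20 (−1.64 ± 0.39). ATF3 was at −1.44, IER2 at −1.10, the centromere gene CENPM at −0.90 and SERTAD1 at −0.96.

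Interferon-stimulated genes had a median of 0.61 over 34 genes at the EC50 dose (percentile 100). Of these, 28 were higher than on both untreated arrays, 0 passed over all genes and 16 were higher when adjusted over the list alone. IFI44L was 2.26, IFI27 2.57 and the antiviral GTPase MX1 1.96 higher, but their untreated SDs were 0.96, 2.34 and 1.18 (log2). ABC transporters had a median of 0.70 over 6 genes (percentile 99.9), with ABCC5 2.83-fold and ABCC2 2.36-fold higher, although another ABCC5 probe set was only 0.28 higher (log2), 0 past the test over all genes and 3 higher when adjusted over the list alone. Matrix proteases had a median of 0.22 (percentile 97.9), which was 0.37 against untreated 1 and 0.07 against untreated 2, including MMP3 at 1.38 higher and MMP1 at 0.95 higher. Immediate early and AP-1 genes had a median of −0.51 over 23 genes (percentile 0), with 15 lower than on both untreated arrays, 0 past the test and 5 lower when adjusted over the list alone. NF-kB and inflammatory genes lay at −0.38 (percentile 0), or −0.22 and −0.49 against untreated 1 and 2, and proteasome genes at −0.15 (percentile 0.32; −0.15 and −0.06 against untreated 1 and 2). Genes of G2/M and mitosis lay at −0.16 (percentile 0.08), NRF2 targets at −0.23 (percentile 0) and cholesterol genes at −0.19 (percentile 0.4; −0.17 and −0.31 against untreated 1 and 2), with 0 past the test in these lists. Histone genes lay at −0.26 (percentile 0.16). Targets of the ATF4 stress response had a median of −0.43 (percentile 0), which was −0.07 against untreated 1 and −0.85 against untreated 2. Tubulin genes had a median of −0.13 (percentile 4.55), inside the central 95%. In total 13 of 49 lists lay outside it, fewer than the 21 for untreated 2 minus untreated 1.

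The doses were compared directly to ask whether their effects differed. FOS was 2.53 higher (log2), MMP3 2.55 higher and IL1RL1 3.10 higher at 10 µM than at the EC50 dose, and TRIM22 was at −2.25 and CFB at −2.04. No gene passed adjusted p 0.05 by limma (0 of 10126, smallest adjusted p = 0.0925), with 450 higher and 921 lower at an unadjusted p under 0.05. By the rule of size, 116 genes were higher and 247 lower at 10 µM, where 132 genes differed at least 2-fold within the untreated pair and 81.6 within simulated pairs. Without a filter limma called 20 higher and 3 lower. The difference between the doses correlated across genes with that between the untreated arrays, which share no array with it (Pearson r = 0.39). Genes are not independent replicates, so no p is given for this r.

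**Figure D3:**
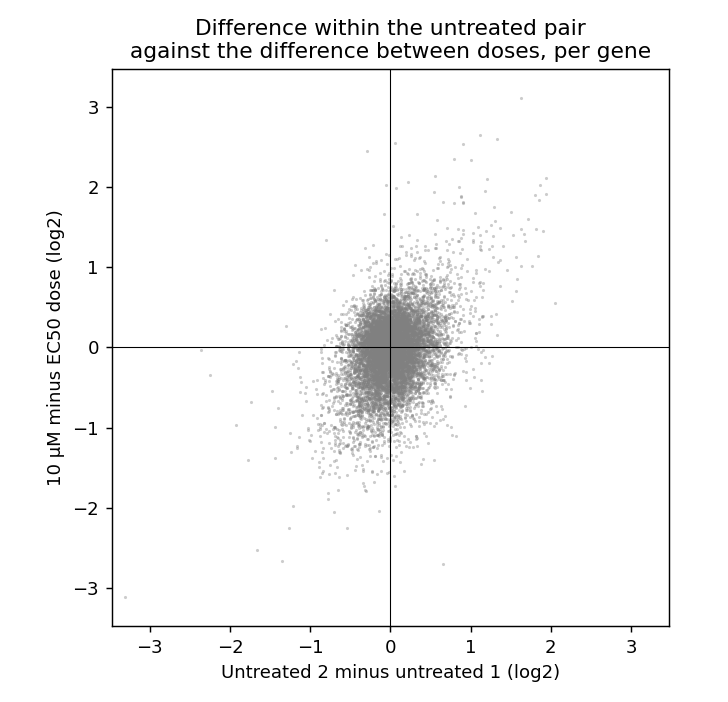
Difference between the 10 µM and EC50 arrays (vertical axis, log2) against that between untreated 2 and untreated 1 (horizontal axis, log2), with 1 point for each of 10126 genes. The cloud leans upward to the right (Pearson r = 0.39, Spearman rho = 0.28).

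Genes that moved alike at both doses were sought by setting both chelidonine arrays against the untreated pair. MMP3, ISG20, AADAC and COL6A1 were at least 2-fold higher than both untreated arrays at each dose, as were ADAM8, CAPRIN2, MTMR11 and OSBPL3, while EGR1 was at least 2-fold lower at each. COL6A1 rests on 1 of 2 probe sets above the filter, as the other was only 0.17 higher at 10 µM and 0.27 at the EC50 dose (log2). ADAM8, MTMR11 and OSBPL3 were named after their values were seen. These 8 higher genes compare with 0.9 from simulated unchanged arrays and 1.16 from independent lists, and the 1 lower gene with 0.75 and 0.02. limma called 0 genes for both arrays together (smallest adjusted p = 0.354), with 457 higher and 89 lower at an unadjusted p under 0.05. That total of 546 lies close to the 506 that chance alone gives.

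Across lists, camera with the preset correlation passed 9 of 49 lists for both arrays together. NRF2 targets were lower (adjusted p = 2.26e-07), as were cholesterol genes (adjusted p = 0.000263), ATF4 targets (adjusted p = 0.00209), keratinocyte differentiation genes (adjusted p = 0.0155), cytosolic ribosomal protein genes (adjusted p = 0.0155) and immediate early genes (adjusted p = 0.0276). Interferon-stimulated genes (adjusted p = 0.000263), matrix proteases (adjusted p = 0.000449) and hypoxia response genes (adjusted p = 0.00440) were higher. None of the 9 held with an estimated correlation, where every list had an adjusted p = 0.983. The estimate was −0.02 for cholesterol and for hypoxia response genes, under the preset 0.01, so a higher correlation was not the reason there. The rest of the 9 had higher estimates than the preset: 0.74 for ATF4 targets, 0.55 for interferon-stimulated genes and 0.51 for immediate early genes. They were 0.26 for NRF2 targets, 0.19 for matrix proteases, 0.10 for ribosomal protein genes and 0.02 for keratinocyte differentiation genes. Where the estimate lay far above 0.01, the adjusted p under the preset may be much too small. With 2 residual degrees of freedom, the setting with an estimated correlation may itself decide little. The immediate early genes had opposite medians at the doses. These were 0.29 at 10 µM (0.26 and 0.03 against untreated 1 and 2) and −0.51 at the EC50 dose. Interferon-stimulated genes did too, with −0.14 at 10 µM (−0.26 and 0.20 against untreated 1 and 2) and 0.61 at the EC50 dose. ATF4 targets lay at 0.03 at 10 µM and −0.43 at the EC50 dose. For these lists the joint test does not show a change alike at both doses. Ribosomal protein genes lay at −0.01 (percentile 26.0) at 10 µM and −0.06 (percentile 5.71) at the EC50 dose. The rest of the 9 had medians of the same sign at both doses.

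Across genes, the differences of the doses from untreated cells correlated with Pearson r = 0.26 (Spearman rho = 0.24), below the 0.33 that simulated unchanged arrays gave through the shared untreated arrays. Their covariance was 0.035 against a simulated 0.025. The sign was shared by 57.4% of genes, against a simulated 60.8%. With no array shared, r was 0.28 when the EC50 array was set against untreated 1 and the 10 µM array against untreated 2, and −0.11 in the converse pairing.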

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

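Tests chosen only after the result was seen were those of the 3′ signal, of a batch shared by arrays, of the fibroblast markers, of the lists set against untreated 2 alone, of the noncoding share and gene span of the higher genes, and of the variance along mean expression; the others were chosen before.

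Several genes lay on opposite sides of both untreated arrays at the doses, which was not tested beyond the direct comparison of the doses that called 0 genes. As 10 µM minus the EC50 dose (log2), FOS was 2.53, KCNMA1 1.99, SERTAD1 1.27, CFB −2.04 and TRIM22 −2.25. The same held for lists, likewise untested: immediate early genes at 0.80, histone genes at 0.59, genes of G2/M and mitosis at 0.43, p53 targets at 0.31, mesenchymal genes at 0.30, autophagy genes at 0.28 and proteasome genes at 0.17. Below 0 were DNA repair genes at −0.21, genes of G1/S and DNA replication at −0.21, basal squamous genes at −0.36, fatty acid and lipid storage genes at −0.43 and ABC transporters at −0.72. For lists, the side was judged by the medians against each untreated array, and some lay near 0 at the EC50 dose. Against untreated 1 they were −0.00039 for autophagy and −0.012 for mesenchymal genes, and against untreated 2 0.0013 for basal squamous genes. Against the untreated mean, mesenchymal genes were higher at both doses, with medians of 0.43 at 10 µM and 0.13 at the EC50 dose. Among 1957 probe sets above the filter that carry no or several gene symbols, and so belong to no comparison, 15 were at least 2-fold higher than both untreated arrays at 10 µM and 71 at the EC50 dose, with 14 and 1 lower.

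The EC50 array had 149 genes at least 2-fold higher and 6 lower, or 333 and 78 against untreated 2 alone and 256 and 13 against untreated 1 alone. Signal of single probe sets alone is argued against for 74 of the 149 genes. Their other probe sets had a median difference of 0.91 (log2), against 1.31 for the probe sets used. The remaining genes had no other probe set above the filter, and with the mean of probe sets 79 genes were higher, so the choice of probe set may add to the count. The normalization before deposit stays open, because quantile normalization and cyclic loess, which left ratios of 15.2 and 21.3, moved no gene by more than 0.37 and 0.09 (log2). These shifts include any change of the probe set chosen for a gene. An excess of unspliced or nuclear RNA stays open: noncoding genes had a median of −0.05 (percentile 5.78), which decides little because they were 3.36% of the higher genes against 1.25% of all, and the difference went with gene span (rho = 0.23). A stronger 3′ bias stays open too, since the beta-actin 3′ to 5′ difference exceeded the highest of the other arrays by 0.30 (log2) and the GAPDH difference by 0.08, as does an untested effect of the dose.

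The untreated arrays were the most alike pair (SD of differences 0.33), but untreated 1 lay nearer the EC50 array than untreated 2 did (0.39 against 0.44), and untreated 2 nearer the 10 µM array (0.34 against 0.43). The difference within the untreated pair correlated across genes with that between the doses at r = 0.389, with no array in common. Offsets that depend on intensity are argued against, because mean expression accounted for only 0.832% and 0.587% of the variance of these differences. The 118 genes of the stress and interferon lists alone are argued against as well, because r was 0.356 without them. Other genes of these programmes may have remained, so the wider programmes stay open. A culture or array batch shared by each untreated array and 1 dose is consistent with these values and stays open, although no label gives a batch.

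At 10 µM, list medians were 0.69 for matrix proteases and 0.56 for senescence factors, and −0.39 for keratinocyte differentiation and −0.16 for basal squamous genes. Fibroblasts in this culture are argued against: the median difference of 11 fibroblast markers was −0.117 (log2), and only 1 of them lay above the olfactory receptor level of 5.93 on this array, PDGFRB at 5.98, named after its value was seen. Against untreated 2 alone, the median was 0.43 for the matrix protease list (percentile 100) and −0.26 for the basal squamous list (percentile 0.16). A state shared with untreated 2 stays open for both lists, because it may be stronger at 10 µM. These percentiles decide little, since 21 of 49 lists lay outside the central 95% within the untreated pair. In that pair the matrix protease list was 0.17 higher (percentile 99.1) and the basal squamous list at −0.07 (percentile 25.5). For the keratinocyte differentiation list the shared state stays open too, because the median against untreated 2 alone was 0.07 (percentile 73.2). An effect of 10 µM chelidonine on the matrix protease and basal squamous lists is a hypothesis from 1 array; repeat cultures of both conditions, processed together, would test it.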

How the results depend on the processing

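The per-dose tests without the other dose array, and the list counts without 1 untreated array, were chosen after seeing the data. No paired analysis was possible because the treated arrays carry no replicate numbers.

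Under the normalization, filter and probe set alternatives, 0 of at most 48 named differences changed sign. This count says little, because the genes were chosen for large differences and a filter leaves their values unchanged. Quantile normalization and cyclic loess moved no EC50 difference by more than 0.37 and 0.09 (log2), so mainly the probe set alternatives could change a sign. The 0.37 is more than quantile normalization alone can give, as sorted values deviated by at most 0.08. The probe set of each gene was chosen anew after each normalization, which can add to the shift. limma called 0 genes at the EC50 dose under the normalization, filter, probe set and variance alternatives. Higher and lower calls at 10 µM (15 and 4) became 2 and 0 after quantile normalization. There the log2 differences of the 19 genes moved by at most 0.05, the prior was 5.75 instead of 6.99 degrees of freedom and their adjusted p ran from 0.00785 to 0.121. They became 72 and 9 without a filter and 29 higher at the olfactory receptor floor. With the mean of probe sets 9 were higher, without shared probe sets the calls were 8 and 2, and without a variance trend 9 were higher. The causes of these were not tested, except that some genes were no longer measured, as given next. Of the 19 genes, 19 were among the calls without a filter, at the olfactory receptor floor and after cyclic loess, 18 with a robust prior, 12 with the mean of probe sets and without a trend, and 9 without shared probe sets. Without shared probe sets, 37 of 48 named differences remained and 3 of these lost their call. The other missing calls were of genes no longer measured above the filter, such as MMP3. With the mean of probe sets 38 remained and 4 lost their call. Without the EC50 array, 20 calls held 19 of the 19 genes. Between the doses limma called 20 and 3 without a filter, and 0 otherwise. For both arrays against the untreated pair, leaving out 1 array gave 0 to 15 higher and 0 to 5 lower calls, the highest without the EC50 array, where the 10 µM array alone remains and genes alike at both doses are no longer tested.

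Counts by size at 10 µM (79 and 34) were 116 to 244 and 54 to 113 with 1 untreated array left out, and at the EC50 dose (149 and 6) 256 to 333 and 13 to 78. They became 264, 185, 633 and 53 at 1.5-fold and 19, 3, 12 and 1 at 3-fold. With the mean of probe sets they were 46, 19 and, at the EC50 dose, 79 higher. There were 142 higher at 10 µM without a filter, and 10 lower at the EC50 dose without shared probe sets.

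Of list medians outside the central 95%, 6 changed sign; sign changes of medians inside it were not counted. Without shared probe sets at 10 µM, histone genes became −0.31 and xenobiotic oxidation genes 0.0033. Without untreated 1 at 10 µM, and without untreated 2, medians ran from −0.12 to 0.41 for NF-kB genes, −0.26 to 0.20 for interferon-stimulated genes and −0.687 to 0.0737 for keratinocyte differentiation genes; at the EC50 dose they ran from −0.393 to 0.0055 for senescence factors. The number of lists outside the central 95% was 18 to 27 at 10 µM and 13 to 18 at the EC50 dose with 1 untreated array left out. The correlation of the doses reversed to −0.11 in the converse pairing, and camera passed 0 lists with an estimated correlation. The causes of these were not tested. Genes near the olfactory receptor floor have signal close to background, which limits their folds.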

Other observations

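Some stress and interferon genes differed within the untreated pair. Between untreated 1 and untreated 2, IFI27, an interferon-induced gene, went from 12.11 to 8.80 (log2), while DDIT4, an inhibitor of mTOR signalling, went from 12.18 to 14.08, DUSP1, a phosphatase of the stress kinases, from 9.76 to 11.70, and DDIT3, a transcription factor of the integrated stress response, from 7.51 to 9.37. As lists, ATF4 targets were 0.70 higher in untreated 2 (median, percentile 100), EGFR ligands and receptors 0.78 higher (percentile 100) and interferon-stimulated genes at −0.43 (percentile 0). In this pair 97 genes were at least 2-fold higher in untreated 2 and 35 lower. A split that put untreated 1 and the EC50 array against untreated 2 and the 10 µM array gave 927 genes at an unadjusted p under 0.05 and 1 past adjusted p 0.05 by limma, against 546 and 0 for chelidonine against untreated. The remaining split gave 81 and 0. With 3 splits of the 4 arrays, the share of splits cannot fall under 0.05.

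Of 13 complement and coagulation genes at 10 µM, 4 lay above and 6 below both untreated arrays, where chance gives 33.3% each. When adjusted over the list alone, 1 was higher and 4 were lower. C1S and CFI, a protease that starts the classical pathway and one that restrains complement, were at −1.11 and −0.94 (log2), while CD55, which protects cells from complement, was 1.73 higher, none past the test over all genes. The list's median was 0.03 (percentile 56.7) and its mean −0.15. Growth arrest genes had a median of 0.45 at 10 µM (percentile 100), or 0.68 and 0.25 against untreated 1 and 2. At the EC50 dose it was −0.13, or 0.20 and −0.13, and within the untreated pair 0.49 (percentile 100), with CDKN1C, a cell cycle inhibitor of another list, 1.64 higher at 10 µM (adjusted p = 0.0927). Oxidative phosphorylation genes lay at −0.04 at 10 µM (percentile 6.71), glycolysis genes at −0.08 (percentile 3.21) and housekeeping genes at 0.00 (percentile 45.5), all inside the central 95%.

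Differences at the EC50 dose went with the length of a gene's span in RefSeq, at Spearman rho = 0.23 across 10123 genes, against −0.12 at 10 µM and 0.02 for the untreated pair. The median difference was 0.13 (log2) among the longest and −0.08 among the shortest of 4 equal groups by span. Genes at least 2-fold higher numbered 27, 42, 38 and 42 from the shortest to the longest group.

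Markers of cells that a FaDu culture should not hold were mostly dim. Above the olfactory receptor level lay 2 of 11 fibroblast, 4 of 10 endothelial, 4 of 11 leukocyte, 1 of 4 erythroid, 4 of 12 hepatocyte, 7 of 11 neuronal and 4 of 12 muscle markers. Their median differences at 10 µM were −0.12, −0.05, 0.06, −0.04, −0.03, −0.17 and −0.12 (log2), in the same order, and at the EC50 dose −0.14, −0.18, −0.08, −0.22, −0.14, −0.14 and −0.23. At 10 µM, 5 of 71 markers were at least 2-fold above the untreated mean and 0 at least 2-fold below it: LCP1, an actin-bundling protein of leukocytes (2.27 higher, adjusted p = 0.136), NEFL of neurons (2.82-fold), TNNT1 of muscle (1.26), CD68 of leukocytes (1.12) and SERPINA1 of hepatocytes (1.06).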
